A study of Mus musculus with 4 samples.

How the data were processed

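Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used with an antibody against SHP (small heterodimer partner, gene Nr0b2), an orphan nuclear receptor that lacks a DNA-binding domain and acts through other transcription factors. The tissue was jejunum and ileum from wild-type C57BL/6 mice and from SHP-knockout mice that had been fasted for 12 h and given chow again for 4 h. Per the labels' protocols, 3 sets of immunoprecipitated and input DNA were analysed, and each set was pooled from 3 mice. The series has 4 samples, an immunoprecipitation and an input for each genotype. A peak list was used for each of the 2 immunoprecipitations. The input samples were not analysed here.

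The submitters' processing notes name CASAVA 1.4, the aligner BWA and the mouse build mm10. The peak caller, its settings, the use of the input as a control, and whether the 3 sets were pooled before calling are not given in the sources used here. Read depth per sample is not given there either, so no interval based on reads could be made. The deposited lists have no header and follow the 10-column narrowPeak layout. The deposited score of the wild-type list ran from 540 to 1000, and that list is named as filtered at an irreproducible discovery rate of 0.05, a measure of agreement between replicate rankings. The deposited score of the knockout list was 10 times the −log10 p, rounded down, and that list is named as one of overlapping peaks. The lists of the 2 genotypes were therefore filtered differently. The seventh column, a deposited signal called the enrichment value here, is the authors' own value for each peak, and its scale is not stated. The deposited −log10 p and −log10 q values were used to describe and filter peaks within a list. Enrichment values, −log10 p and scores were not read as differences in binding between genotypes, because they depend on depth and filter. Where values of both lists are given together, they only describe the lists.

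Positions were converted to 1-based coordinates. Gene positions came from a RefSeq table of the assembly GRCm38.p6, which has the coordinates of mm10, with 49943 genes on chromosomes 1 to 19, X and Y, of which 21887 are protein-coding. That table gives the start and end of each gene without strand, exons or sequence. Distances were therefore measured from each summit to the nearest end of a gene, and which end is the transcription start is not given in the annotation used. The design fixed before the data were examined had named transcription start sites, exon and intron classes, and transcription factor motifs. The first was replaced by gene ends. The classes were reduced to within 1 kb of an end of a protein-coding gene and elsewhere inside such a gene. The other classes were inside or within 1 kb of an end of a gene of another type, and the rest, called between genes. Motifs, matching on promoter GC content, and the exclusion of assembly gaps were not run, since they need the genome sequence.

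Random expectation came from 1000 placements in which every peak was moved on its own chromosome with its width and summit offset kept. The smallest p that these placements can give is 0.000999 one-sided and 0.002 two-sided. Random distances to gene ends, given as a median and by distance class, came from a single further placement. A gene was counted as having a peak where a wild-type summit lay within 5 kb of either end, so that one summit could count for several neighbouring genes. The 24 gene lists, written before the data were examined, held 950 names, of which Pnpla4 and Trac were not matched to a protein-coding gene. Each list was tested against all other protein-coding genes with a two-sided Fisher's exact test and Benjamini-Hochberg adjustment over the 24 lists, and was called at an adjusted p under 0.05. Shares carry 95% exact (Clopper-Pearson) binomial intervals, which cover counting error only. Enrichment values of peaks near and away from gene ends were compared by a two-sided permutation test of the difference in medians with 100000 resamples. With 1 list per genotype there were no replicate lists to compare, and no test of wild type against knockout was made. Peaks and genes are not independent replicates, and the p-values describe these lists only. On simulated data with 21887 genes, the list test called 80 of 80 lists with raised occupancy and 0 of 400 lists without it, over 20 simulations. There, peaks were placed at random, peaks were added at many members of the raised lists, and the other lists were random genes. The simulations therefore check that the test runs as intended. They do not measure its power or false calls at the occupancy of the real lists.

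Genes were named by a rule fixed before the data were examined. It takes the genes at the 15 highest enrichment values within 5 kb, up to 3 members of each list by enrichment value, the gene nearest to each knockout peak, and Nr0b2, Fgf15, Tfeb, Pnpla2, Npc1l1, Ulk1 and Atg3. Some genes that the rule names are not reported here. Alternatives covered stricter peak thresholds, other distances, assignment to the nearest gene only and other overlap rules. They also covered random gene lists matched on neighbouring genes, and removal of wild-type peaks near a knockout peak. Further alternatives, added after the data were seen, were a local shift of peaks, autosomal genes or peaks only, curated genes without chemosensory receptor families, and random lists matched on gene length. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.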

Results

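To map where SHP sits on chromatin in the fed intestine, SHP ChIP was performed on jejunum and ileum of wild-type mice and of SHP-knockout mice, which lack the antigen and so show the background of the antibody. All mice had been fasted for 12 h and refed for 4 h, so fed and fasted states were not compared. There was 1 peak list for each genotype, and no list for each replicate set. The wild-type list held 5775 non-overlapping peaks that covered 6.19 Mb of the genome. Their median width was 978 bp (interquartile range 713 to 1328 bp). The median enrichment value, as deposited by the authors, was 5.65 (interquartile range 4.93 to 6.46), and the median −log10 p was 14.8. Read depth was unknown. Of the wild-type peaks, 5190 (89.9%) had exactly the same pair of enrichment value and −log10 p as at least 1 other peak, and the commonest pair, 5.10 and 12.0, occurred in 53 peaks.

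SHP immunoprecipitation gave 5775 peaks in wild-type intestine and 7 peaks in knockout intestine, a ratio of 825. The knockout peaks covered 1647 bp in all and had a median width of 211 bp. Of these sites, 3 lay beside transfer RNA genes, which are short, highly transcribed genes read by RNA polymerase III. These were chromosome 7:120835409–120835649, 11 bp from n-TLtag1 and nearest to the protein-coding gene Gm5737, chromosome 14:51064836–51065046, 22 bp from n-TPagg4 and nearest to Olfr750, and chromosome 11:97988214–97988419, at n-TCgca55 and nearest to Arl5c. Their enrichment values were 6.16, 4.61 and 5.43. Another site, at chromosome 2:163644902–163645151, lay inside Serinc3, 94 bp from an end of the gene, with an enrichment value of 5.17. The remaining sites lay outside genes, 7510 bp from Rdx at chromosome 9:52096202–52096375, 26381 bp from Vmn2r117 at chromosome 17:23433217–23433585, and 11796 bp from Gm14496 at chromosome 2:182012811–182013006. Their enrichment values were 5.12, 5.12 and 2.84.

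The knockout sites near Gm5737, Serinc3 and Olfr750 were also in the wild-type list, where their enrichment values were 5.19, 6.56 and 4.93. Thus 3 of 7 knockout peaks shared at least 1 bp with a wild-type peak, against a mean of 0.028 and a maximum of 1 in 1000 random placements (one-sided permutation p = 0.000999, the smallest possible). In the wild-type list these were 3 of 5775 peaks. Within 100 bp of a transfer RNA gene end lay 3 of 7 knockout summits and 26 of 5775 wild-type summits. The random placements gave 0 of the knockout summits and a mean of 0.248 of the wild-type summits there. The ratio of peak numbers has no test, because each genotype had 1 list and the lists were filtered differently. At the median −log10 p of each list or above, 2915 wild-type and 4 knockout peaks were left. That threshold keeps a similar share of any list, so it cannot test the ratio. The weakest knockout −log10 p was 8.95, and 253 wild-type peaks lay below it, a count that also depends on depth and filter.

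**Figure D1:**
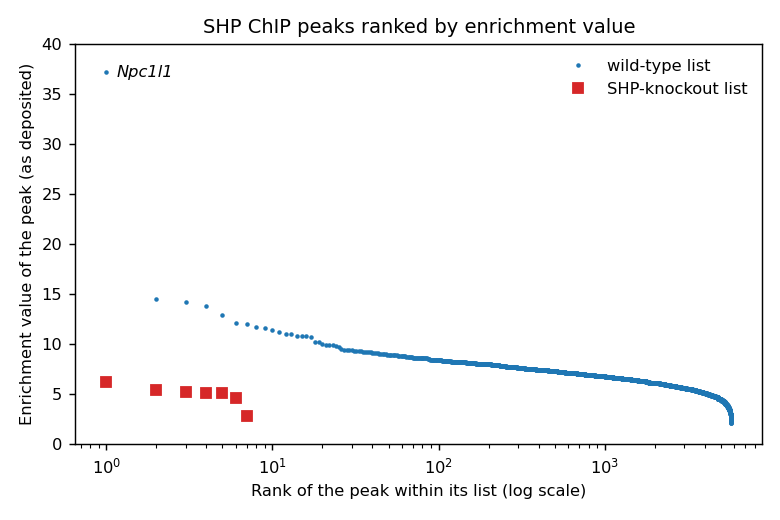
Enrichment value of each peak, as deposited, against its rank within its own list (log scale), for the 5775 wild-type peaks (blue points) and the 7 knockout peaks (red squares). The Npc1l1 peak at 37.2 stands above all others, and the knockout values run from 2.84 to 6.16.

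Wild-type SHP peaks lay mainly at the ends of genes. Of 5775 summits, 4044 (70.0%, 95% exact interval 68.8 to 71.2) were within 1 kb of an end of a protein-coding gene, against a mean of 3.29% (range 2.46 to 4.16) in random placements. That share was 21.3 times the random one (two-sided permutation p = 0.002, the smallest possible). The median distance from summit to gene end was 282 bp, against 46552 bp in a single random placement of the peaks. Among 3369 genes of 10 kb or more with a summit within 1 kb, 3332 (98.9%) had it at one end only and 37 at both. No random expectation was made for that share, so it does not show a preferred end. A further 1349 summits (23.4%) lay elsewhere inside protein-coding genes. Another 189 (3.27%) lay inside, or within 1 kb of an end of, genes of other types, and 193 (3.34%) lay between genes. The random placements put 39.2%, 9.32% and 48.2% of summits in these classes, and each difference had p = 0.002 (two-sided permutation). When peaks were moved by only 100 to 500 kb, a shift chosen after the data were seen, the random share near gene ends was 6.44%.

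Peaks near gene ends were slightly lower in enrichment value than the other peaks. Medians were 5.64 over 4044 peaks and 5.79 over 1731 peaks, a difference of -0.151 (two-sided permutation p = 0.0001). By −log10 p the order was reversed, with medians of 15.3 near gene ends and 14.2 elsewhere (difference 1.06, permutation p = 2e-05), so the direction depended on the measure.

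**Figure D2:**
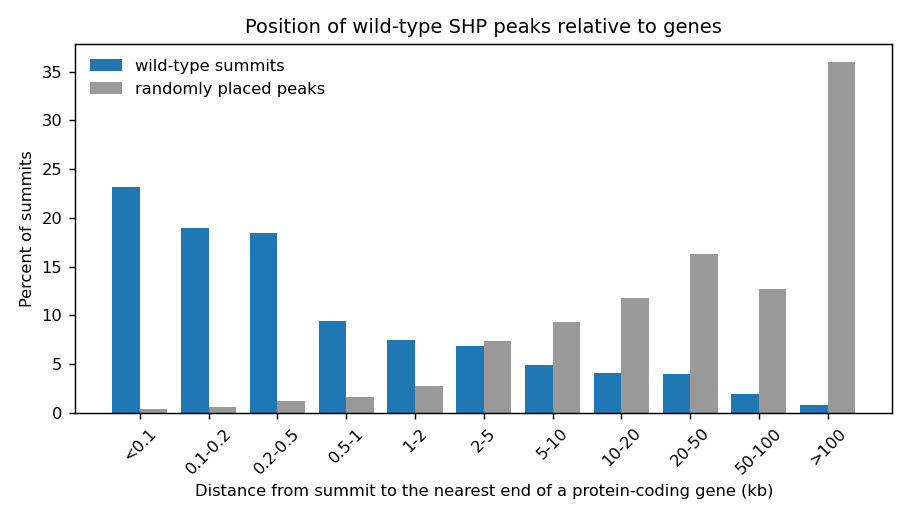
Percentage of summits in each class of distance to the nearest end of a protein-coding gene (kb), for the 5775 wild-type peaks (blue bars) and for a single random placement of them (grey bars). Wild-type summits are most frequent below 0.1 kb (23.2%), where that placement puts 0.416%.

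The strongest wild-type peak lay at Npc1l1, the sterol transporter of the enterocyte brush border through which dietary cholesterol is taken up. It spanned chromosome 11:6229840–6231244, overlapped one end of the gene (6211011–6230245), and had its summit 780 bp outside that end. Its enrichment value was 37.2, which was 2.58 times the second highest value in the list (14.5) and 6.59 times the median. No knockout peak lay within 10 kb, but the knockout list held only 7 peaks and was filtered differently. Its lack of a peak here therefore cannot show that the Npc1l1 peak depends on SHP. The next peaks within 5 kb of a gene end were at Denr, a factor in ribosome recycling and reinitiation (14.2), Cdk12, a kinase of RNA polymerase II (13.8), Atp5pb, a subunit of ATP synthase (12.9), Ube2d3, a ubiquitin-conjugating enzyme (12.1), and Ireb2, a regulator of iron metabolism (12.0). Micos10 (11.7), Banp (11.6), Eif4a3 (11.5), Supt5 (11.2), Hip1r (10.98), Puf60 (10.98), Psmd5 (10.8), Ssbp1 (10.8) and Ccdc107 (10.7) followed. Within 1 kb of a gene end, Puf60 had 7.20 and Ireb2 and Banp had no peak (summits 1037 and 2708 bp from an end). Of the wild-type peaks, 401 had an enrichment value under 4, 3166 from 4 to 6, 2022 from 6 to 8 and 167 from 8 to 10.

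**Figure D3:**
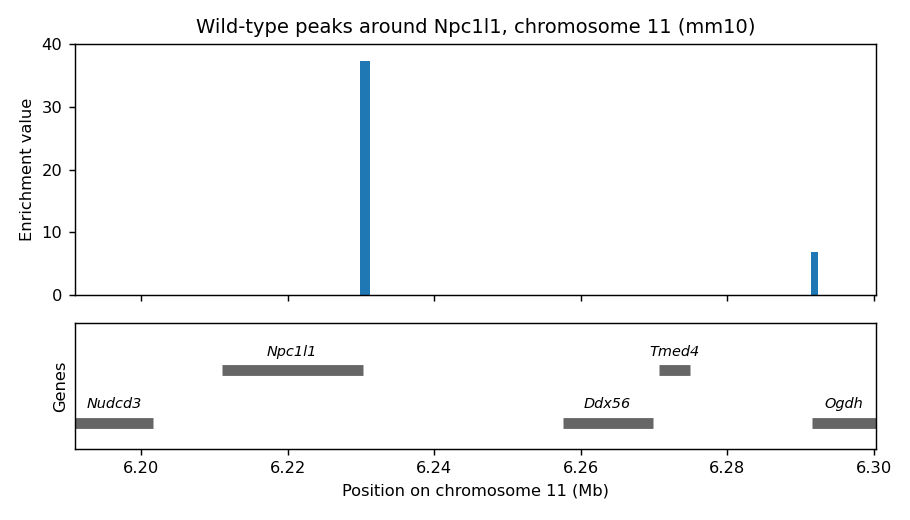
Map of chromosome 11 from 6191011 to 6300245 (mm10, position in Mb), with wild-type peaks as bars to scale whose height is the enrichment value (upper panel) and protein-coding genes as grey boxes (lower panel). The peak at the end of Npc1l1 reaches 37.2, and the peak at the end of Ogdh reaches 6.86.

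Genes named by the study's FGF15, SHP and TFEB theme were then examined. Tfeb, which encodes a transcription factor that activates autophagy and lysosome genes, had a peak at chromosome 17:47736890–47738992 with the summit 67 bp inside one end of the gene. Its enrichment value of 3.74 ranked 5509 among 5775. Pnpla2, which encodes adipose triglyceride lipase, had a peak at chromosome 7:141455012–141456418 with a value of 6.26 and the summit 12 bp inside the gene. Ulk1, a kinase that starts autophagy, had a peak at chromosome 5:110808007–110810394 with a value of 5.10 and the summit 119 bp inside. No summit lay within 5 kb of Nr0b2, which encodes SHP itself, of Fgf15, the ileal hormone induced by bile acids, or of Atg3, an enzyme of LC3 lipidation. The nearest summits to these genes were 7456, 14284 and 554440 bp away.

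Genes of autophagy and of the lysosome had SHP peaks more often than other genes. Genome-wide, 5778 of 21887 protein-coding genes (26.4%) had a summit within 5 kb of an end. Of the autophagy machinery, 29 of 62 genes (46.8%, 95% exact interval 34.0 to 59.9) had one (odds ratio 2.46, Fisher's exact test, adjusted p = 0.00286). The highest enrichment values were at Vps11 (8.65, summit 3657 bp outside the gene), a subunit of the complexes that tether vesicles to lysosomes, Ambra1 (7.56), which acts with the Beclin complex, and Sqstm1 (7.19), the autophagy receptor p62. Of the lysosome genes of the CLEAR network, the gene set regulated by TFEB and its relatives, 31 of 70 (44.3%, 32.4 to 56.7) had a peak (odds ratio 2.22, adjusted exact p = 0.00432). Scarb2 (9.03), Scpep1 (8.31) and Rragc (8.15) had the highest values. The lysosome result was no longer called with only the peaks at or above the median −log10 p (odds ratio 1.20, adjusted exact p = 0.663), and over the 9 alternatives its adjusted p ran from 0.000234 to 0.663 (exact or permutation).

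Among lipid genes, the fatty acid oxidation and ketogenesis list stood above the genome, with 20 of 43 genes (46.5%, 31.2 to 62.3; odds ratio 2.43, adjusted exact p = 0.0111). Hadha and Hadhb, which encode the trifunctional protein of beta-oxidation, shared a peak with a value of 7.64, and Ucp2 had one of 7.25. At the median −log10 p or above this list was not called (adjusted exact p = 0.127, the highest of 9 alternatives, of which the lowest was 0.000705). Lipolysis and lipid droplet genes had peaks at 9 of 29 members (31.03%, adjusted exact p = 0.598), led by Ldah (8.30), Lpin1 (6.66) and Plin5 (6.66). Fat absorption and chylomicron assembly genes had them at 8 of 35 (22.9%, adjusted exact p = 0.706), where Agpat2 (7.53) and Lpcat3 (6.40) came after Npc1l1. Cholesterol genes had them at 12 of 37 (32.4%, adjusted exact p = 0.546), where Hmgcs1 (9.96) and Sqle (6.87), both enzymes of sterol synthesis, came after Npc1l1. Fatty acid and triglyceride synthesis had 9 of 27 (33.3%, adjusted exact p = 0.503), led by Pklr (7.34), Acly (6.48) and Acss2 (6.11). Bile acid signalling and transport had 3 of 30 (10%, 2.11 to 26.5; odds ratio 0.309, adjusted exact p = 0.0784), namely Klb (6.11), the FGF15 co-receptor, Vdr (5.41) and Mafg (4.76). That list passed the threshold, as lower, against curated genes without chemosensory receptors, a background chosen after the data were seen (adjusted exact p = 0.0425). This was the lowest adjusted p of 9 alternatives (exact or permutation), of which the highest was 0.622. Within 50 kb the direction of the bile acid list was reversed, with 18 of 30 genes (odds ratio 1.61, adjusted exact p = 0.275).

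Nuclear receptor and cofactor, immediate early, circadian clock and insulin, mTOR and growth-factor genes had peaks more often than other genes, and the lists of glucose and one-carbon metabolism did not pass the test. The other genes were not matched on expression in this tissue. Cytosolic ribosomal protein genes, given below, had peaks at 66.2% of members, so these calls do not mark the lists as particular targets of SHP. Nuclear receptors and their cofactors had peaks at 38 of 65 genes (58.5%, 45.6 to 70.6; odds ratio 3.94, adjusted exact p = 6.09e-07). Nr5a1 (7.69, summit 4166 bp from an end), Crtc2 (7.65) and Ehmt2 (7.54) had the highest values. Within 1 kb, 25 of the 65 genes had peaks (odds ratio 2.41, adjusted exact p = 0.00352). Immediate early genes had them at 19 of 26 (73.1%, 52.2 to 88.4; odds ratio 7.59, adjusted exact p = 7.07e-06), led by Jun (8.73), Klf6 (8.60) and Klf4 (8.16). Circadian clock genes had 14 of 22 (63.6%, 40.7 to 82.8, with an odds ratio of 4.89 and adjusted exact p = 0.00128). Per3 (6.86) and Dbp (6.52) were among the highest. The odds ratio of the clock genes was 3.20 within 1 kb (10 of 22) and 8.99 with the nearest gene only (16 of 22). Insulin, mTOR and growth-factor genes had 20 of 39 (51.3%, 34.8 to 67.6; odds ratio 2.94, adjusted exact p = 0.00304), with Irs2 (8.19) and Rictor (7.56) highest. The insulin list was not called at the median −log10 p or above (odds ratio 1.49, adjusted exact p = 0.457, the highest of 9 alternatives, of which the lowest was 0.000419). Gluconeogenesis and glycolysis had 10 of 32 (31.3%, adjusted exact p = 0.598), led by Khk (7.29), Aldoa (7.03) and Gpi1 (6.37). One-carbon genes had 9 of 31 (29.0%, adjusted exact p = 0.706), led by Mthfd2 (8.16) and Mat2b (7.75).

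Cytosolic ribosomal protein genes and genes of the unfolded protein and stress response also had peaks more often than other genes, and the respiratory chain did not pass the test. Cytosolic ribosomal proteins had them at 51 of 77 genes (66.2%, 54.6 to 76.6; odds ratio 5.51, adjusted exact p = 6.66e-12), with Rps29 (8.65) and Rpl12 (8.46) among the highest. The unfolded protein and stress response had 21 of 32 (65.6%, 46.8 to 81.4; odds ratio 5.34, adjusted exact p = 2.26e-05), with Manf (8.66), Herpud1 (7.99) and Calr (7.43) highest. The mitochondrial respiratory chain had 19 of 58 (32.8%, adjusted exact p = 0.444), where Atp5pb was followed by Cyc1 (9.10) and Cox6a1 (8.76).

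Markers of differentiated cells had peaks at few of their members, and of these lists the immune and hepatocyte markers passed the test as lower than other genes. Enterocyte markers had them at 5 of 41 genes (12.2%, 4.08 to 26.2; odds ratio 0.387, adjusted exact p = 0.0904), among them Anpep (7.21), Myo7b (6.15) and Vil1 (5.68), of the brush border. Goblet, Paneth, enteroendocrine and tuft markers had 4 of 34 (11.8%, 3.30 to 27.5; adjusted exact p = 0.0904), among them Gip (6.87), Pou2f3 (6.12) and Trpm5 (5.60). Neither list was called. The secretory list was called as lower within 1 kb (adjusted exact p = 0.0146), with the nearest gene only (0.0327) and against curated genes (0.0425), and its adjusted p ran up to 0.515 over 9 alternatives. The enterocyte list was called as lower against curated genes (adjusted exact p = 0.0334) and length-matched genes (permutation p = 0.044), and its adjusted p ran up to 0.391. Immune markers had 2 of 33 (6.06%, 0.743 to 20.2; odds ratio 0.180, adjusted exact p = 0.0111), namely Cd79a (6.07) and Tbx21 (4.69). Hepatocyte markers, of an organ that was not collected, had 1 of 30 (3.33%, 0.0844 to 17.2; odds ratio 0.0960, adjusted exact p = 0.00432), at Apof (5.94). Immune and hepatocyte lists were not called within 50 kb (adjusted exact p = 0.281 and 0.0637) or at the median −log10 p or above (0.174 and 0.214). Their lowest adjusted p over the 9 alternatives was 0.00612 and 0.00207 (exact or permutation). Stem and cycling cell markers had 10 of 29 (34.5%, adjusted exact p = 0.503), with Prom1 (7.06), Ascl2 (6.70) and Cdk1 (6.60) highest. Smooth muscle and stromal markers had 5 of 33 (15.2%, adjusted exact p = 0.27, and 0.038 at the median −log10 p or above), with Kit (6.58), Sox10 (5.88) and Lmod1 (5.74) highest, and neuronal genes 6 of 33 (18.2%, adjusted exact p = 0.465), with Nefm (6.77), Map2 (6.48) and Grin1 (6.30) highest. Of the 84 named genes with a peak within 5 kb, 67 had one within 1 kb. Besides Ireb2, Banp and Vps11, those with none were Plin5, Klb, Aldoa, Mat2b, Nr5a1, Dbp, Manf, Cox6a1, Myo7b, Gip, Trpm5, Cd79a, Sox10 and Nefm. Among those with a weaker peak within 1 kb were Acly (4.67), Gpi1 (4.86), Crtc2 (6.50) and Ehmt2 (6.64). With peaks within 50 kb counted, 12 of the 84 had a higher value, and 3 of these, Tfeb (6.66), Vdr (8.97) and Mafg (8.27), by over 1.5 times. In all, 9 of the 24 lists were called as higher and 2 as lower, and 13 had an unadjusted p under 0.05.

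**Figure D4:**
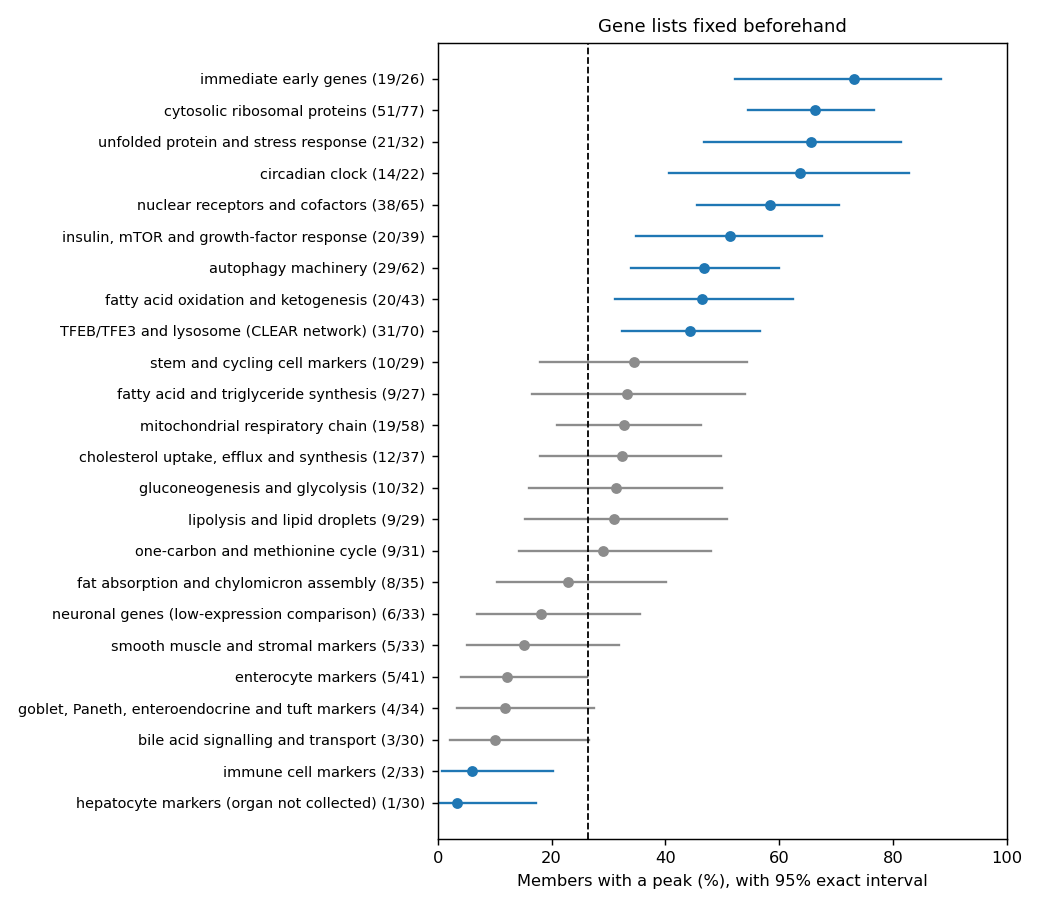
Percentage of each list's members with a wild-type summit within 5 kb of a gene end (points) with 95% exact intervals (lines) for the 24 lists, with the number of members with a peak in brackets. Blue lists passed the test, grey lists did not, and the dashed line is the genome-wide 26.4%; immediate early genes are highest at 73.1% and hepatocyte markers lowest at 3.33%.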

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

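Alternatives were fixed before the data were examined, except the local shift, autosomal genes or peaks only, curated genes and length matching. The shares near gene ends, the 4 position classes and the overlap of knockout with wild-type peaks stayed on the same side under every alternative run. Thresholds taken from each list itself left 2915 wild-type and 4 knockout peaks (median −log10 p) or 1447 and 2 (75th percentile of the enrichment value). Such thresholds keep a similar share of any list, so they cannot test the ratio of peak numbers. By −log10 p, the difference between peaks near gene ends and others was 1.06, reversed from -0.151; the cause was not tested. Removing wild-type peaks near a knockout peak left the number of members with a peak unchanged in every list, so it could hardly move a result. With that alternative included, of 216 list results 192 kept direction and side of the threshold. A call was gained by 7 and lost by 7, and 10 results of lists not called crossed an odds ratio of 1. These were fat absorption within 1 kb (1.14), within 50 kb (1.43), with the nearest gene only (1.34) and at the median −log10 p or above (1.20), one-carbon genes within 1 kb (0.920), with the nearest gene only (0.980) and against curated genes (0.992), gluconeogenesis and glycolysis within 1 kb (0.885), bile acid genes within 50 kb (1.61) and the respiratory chain with the nearest gene only (0.699). At the median −log10 p or above, which leaves fewer peaks, the odds ratios were 1.20 for lysosome genes, 1.99 for fatty acid oxidation, 1.49 for insulin and mTOR, 0.180 for immune and 0.199 for hepatocyte markers, all not called, and 0 for smooth muscle and stromal markers (adjusted exact p = 0.038); 6 lists were higher and 1 lower. Within 50 kb, immune (0.614) and hepatocyte markers (0.390) lost their calls and 0 lists were lower. Secretory cell markers were called within 1 kb (0.116), with the nearest gene only (0.210) and against curated genes (0.323). Curated genes gave 5 lower lists, with bile acid genes at 0.269 and enterocyte markers at 0.336. Length matching called enterocyte markers at a ratio of 0.435. For these the cause was not tested. Of the 84 named genes with a peak within 5 kb, 17 had none within 1 kb and 13 had their strongest peak below the median −log10 p; of the values left under the alternatives, 202 stayed the same and 20 moved. Matching on promoter GC content and all motif alternatives were not run. Depth is not given in the sources used here, so its limits on calls near the threshold are open. No paired analysis was possible because each genotype had 1 peak list.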

Other observations

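The tests here were chosen after the results were seen, except the comparison with genes that have as many neighbours. Protein-coding genes were grouped by the letters at the start of their symbol, with at least 15 genes per group, and 161 groups were tested with Fisher's exact test and Benjamini-Hochberg adjustment. Of these, 15 had peaks more often than other genes and 31 less often. Among the former were the Klf transcription factors (12 of 17, 70.6%, adjusted exact p = 0.00177), the Ptpn tyrosine phosphatases (12 of 17, 70.6%, 0.00177), the Vps genes of vacuolar protein sorting (22 of 35, 62.9%, 8.58e-05), the Zbtb zinc-finger genes (25 of 41, 60.98%, 6.64e-05) and the Polr subunits of RNA polymerases (16 of 28, 57.1%, 0.00523).

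Among the families with fewer peaks, named here after their values were seen, cytochrome P450 genes (Cyp) had them at 5 of 99 (5.05%, adjusted exact p = 2.38e-06), Ugt glucuronosyltransferases at 0 of 22 (0.0117), Ces carboxylesterases at 0 of 19 (0.0259) and Defa defensins of Paneth cells at 0 of 29 (0.00184). Other families of metabolising enzymes did not pass the test, with Sult sulfotransferases at 1 of 21 (adjusted exact p = 0.0677) and Aldh aldehyde dehydrogenases at 6 of 21 (0.885). Olfactory receptors (Olfr) had peaks at 0 of 1110 and vomeronasal receptors (Vmn) at 1 of 355. Solute carriers (Slc) did not pass the test, with 96 of 375 (25.6%, adjusted exact p = 0.862).

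The Npc1l1 peak stood far from all others, with a −log10 p of 257 against 73.4 for the next. An artefact present in both genotypes could give such a peak, and the knockout list held 0 peaks within 10 kb. That list was filtered differently and holds 7 peaks in all, so the test leaves this open. A contaminating PCR product might also do so, and such a product would be expected to give a narrow region. The region was 1405 bp wide, wider than 78.8% of wild-type regions, but its summit lay 219 bp from one edge, so the product cannot be told apart from binding of SHP without the reads.

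Chromosome X had few peaks, at 19 of its 966 protein-coding genes (1.97%, 95% exact interval 1.19 to 3.05), against 27.9% of autosomal genes and 20.8% on the lowest autosome. A different mix of genes on the chromosome is argued against as the cause, since 0 of 28 X-linked members of the fixed lists had a peak against 348 of 890 autosomal members (39.1%, two-sided Fisher's exact p = 1.41e-06). Fewer reads per site on X could also lower the number of peaks, as with a single X in male mice, but the sex of the mice is not given in the labels and the test left this open. Over the 35 X peaks with autosomal peaks of the same −log10 p, the median difference in enrichment value was -1.93, opposite to what the explanation needs. Of these peaks, 15 were higher and 20 lower (permutation p = 0.0001, the smallest that 10000 draws can give). That direction rests on a cluster of 19 peaks within 38.5 kb, with values of 3.03 to 6.22, of which all 18 comparable ones were lower. The permutation test counts these neighbouring peaks as independent, so its p-value does not describe the chromosome. Without the cluster, 15 of 17 peaks were higher (median 1.2, permutation p = 0.0001), the direction that the explanation needs. This split was made after the values were seen, and no biological explanation was tested.

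Autophagy and lysosome genes together had peaks at 60 of 132 (45.5%, 36.8 to 54.3). Dense gene neighbourhoods as the whole cause are argued against for the autophagy list, which was still called against random genes with as many neighbours (adjusted permutation p = 0.00411, within a range of 0.00252 to 0.038 over 9 alternatives). Occupancy common to broadly active genes may account for the level, since ribosomal protein and respiratory chain genes together had peaks at 70 of 135 (51.9%, 43.1 to 60.5), with an odds ratio of 0.774 for autophagy and lysosome genes against them (two-sided Fisher's exact p = 0.328). Taken singly, the respiratory chain stood at 32.8% and ribosomal proteins at 66.2%, so the comparison rests on the latter. These genes were not chosen by expression in this tissue, and a role of SHP specific to autophagy genes was not tested. Whether occupancy common to broadly active genes accounts for the other lists called as higher was not tested either.

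Among summits over 5 kb from any end of a protein-coding gene, the highest enrichment value was 14.5, at chromosome 8:91820296–91820735, 18941 bp from Irx3 and 4496 bp from an end of Gm39223, a gene not annotated as protein-coding. These peaks were chosen after their values were seen. The next such peaks were 10.8 beside the transfer RNA gene n-TEctc11 (27 bp, chromosome 13:21160705–21160919) and 9.87 at chromosome 18:11288555–11288768, 203005 bp from Gata6. The cluster of 19 of the 36 X peaks lay within 38.5 kb at chromosome X:169981770–170020237, 6 of them inside Mid1, and 4 peaks lay on chromosome Y between 90723669 and 90744898.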
